A study of Mus musculus with 6 samples.

How the data were processed

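The series holds RNA from mouse (strain C57BL/6) alveolar macrophages, the resident phagocytes of the lung airspace, in which the transcription factor C/EBPβ was overexpressed. Per the labels, 3 libraries (group CEBPb) come from such cells and 3 (group CEBPb-A) from such cells after an adenovirus carrying A20. A20 is the ubiquitin-editing enzyme encoded by Tnfaip3 and a known brake on NF-κB signalling. Per the labels' protocols, the isolated cells were given the adenovirus indicated and were snap frozen, RNA was taken with TRIzol, and stranded libraries were made with a KAPA kit from 1 µg of total RNA. An A20 adenovirus is named for CEBPb-A; which virus the CEBPb cells were given, whether a control virus was among them, and whether C/EBPβ came by virus are not stated in the sources used here. No group without C/EBPβ overexpression was analysed here. The labels call the libraries replicates and do not say that they come from separate animals or cultures, so every p-value measures only the spread between these libraries, which may be technical.

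The authors deposited 1 table of FPKM values (fragments scaled by gene length and by the total of mapped fragments) for the 6 libraries, per the file headers. It lists 10539 genes, all of the type protein coding, each with a versioned Ensembl identifier, a symbol, a locus and a strand. The genome build is GRCm38, per the submitters' processing notes. The aligner, the program that computed FPKM, the annotation release and the rule by which these genes were listed are not given in the sources used here. The file header announces FPKM in 9 columns, and the table used here has 6, all of which were used. FPKM divides by the authors' own gene length and library total, so differences between libraries in fragment length, RNA integrity or capture of long transcripts stay in the values. How multi-mapped reads were divided among near-identical genes is also not given.

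Sequencing depth is unknown: FPKM values of low genes with 1 annotated transcript showed no clear whole-read steps, with a highest periodicity of 0.137 to 0.167 per library against 0.158 to 0.186 in 5 random sets. No counting interval can therefore be given, and precision was judged only from the spread of 3 libraries per group. The listed genes' FPKM summed to between 278907 and 313215 per library.

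Genes with a mean FPKM of at least 1 over the 6 libraries were tested (9617 genes). Values were put on the log2(FPKM + 1) scale, which understates the change of low genes, and limma (version 3.58.1, R 4.3.3) was fitted with an intensity trend, CEBPb-A minus CEBPb, with no covariate. P-values were two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05 and no minimum fold change. Means and SDs are of FPKM, fold changes and their standard errors (SE) are from limma on the log2 scale. Tnfaip3 and Cebpb, the genes of A20 and of the overexpressed C/EBPβ, were also compared by an exact two-sided permutation test of the group means, whose smallest possible p with 3 against 3 is 0.1. A count of genes whose groups do not overlap is given beside the 10% that chance gives.

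Of 37 gene lists, written from textbook knowledge, 29 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, two-sided and adjusted over the 29 lists. They cover NF-κB feedback and subunits, partners of A20, cytokines, chemokines, interferon responses, antigen presentation, C/EBP-linked genes, macrophage identity and activation, Fc receptors and complement, Toll-like receptors, early response genes, lipid and energy metabolism, stress responses, cell cycle, lysosome, matrix, RNA quality and other cell types. Members past the threshold were counted over all genes tested and with p adjusted over the list alone. The latter is not corrected for the number of lists searched. The camera test with the correlation estimated per list and fry, a rotation test, were run beside it. With an estimated correlation, camera rests on the few residual degrees of freedom that 6 libraries leave. A call can then be lost even where members are not correlated. Fry's directional p asks whether a list moves one way on balance. Its mixed p asks whether members change in either direction, and neither compares a list with other genes.

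The main test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Tnfaip3, Cebpb, the genes past the threshold whose groups do not overlap (skipping symbols of the form Gm plus digits), the 5 genes with the smallest p each way that did not pass, and up to 4 members per list by p, with up to 2 by FPKM for lists of other cell types. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, upper-quartile and median-of-ratios scaling, quantile normalization, limma without the trend or with a robust prior, the replicate number as a block, each library left out in turn, and a fold change of at least 1.5. Added after seeing the data were the removal of each library's trend over transcript length and GC content (natural splines with 4 degrees of freedom), the same without CEBPb-A replicate 3, and the exclusion of genes whose exons overlap another listed gene on the same strand. Transcript length, GC content and overlaps came from GENCODE release M21, in which 10516 of the 10539 identifiers were found, 9603 of them at the deposited start and end. Coordinates are the deposited ones. Figures and the joining of tables used Python.

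The test was tried on simulated values with 200 of 9576 genes changed. Each gene's fitted SD served as its true SD, and values were drawn independently for each gene, without structure shared by libraries. In this simulation limma recovered 55.2% of genes changed 1.5-fold, 80.6% at 2-fold and 93.7% at 4-fold, with 6 unchanged genes called. These shares may be too high for the real libraries. A simulated shift of 0.3 (log2) in the NF-κB feedback list was recovered, and 0 of 28 other lists were called. Genes were drawn independently here too, so that count does not show how often correlated genes give false list calls.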

Results

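Transcript levels were measured by RNA sequencing in mouse alveolar macrophages that overexpressed C/EBPβ, in 3 libraries labelled CEBPb and 3 labelled CEBPb-A, the latter after an adenovirus carrying A20. The comparison asks what A20 delivery does to gene expression in such cells. The most abundant transcript in each of the 6 libraries was Lyz2, the lysozyme of macrophages, at 19554 to 29717 FPKM, and the median listed gene lay between 6.12 and 6.63 FPKM. Depth is unknown, since the values are FPKM. Pearson correlations of log2(FPKM + 1) between libraries ran from 0.973 to 0.990 over 9617 genes, and CEBPb-A replicate 3 stood apart from the other 5 libraries on the first principal component (score 25.7 against −11.7 to −0.095, 44.3% of the variance).

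Tnfaip3, the gene of A20 (ENSMUSG00000019850.11, GRCm38 chromosome 10, 19000910 to 19015657), was not higher in the libraries labelled CEBPb-A. Its level was 10.2 ± 4.53 FPKM there and 15.2 ± 5.64 in CEBPb (SD, n = 3 each). The 3 libraries labelled CEBPb-A stood at 7.94, 15.5 and 7.32 FPKM and the 3 of CEBPb at 8.76, 17.7 and 19.2. The difference did not pass either test (log2 fold change −0.53, SE 0.34, limma adjusted p = 0.606; exact permutation p = 0.2, smallest possible 0.1). Cebpb (ENSMUSG00000056501.3, chromosome 2, 167688915 to 167690418) had 411 ± 70.5 FPKM in CEBPb-A and 429 ± 66.6 in CEBPb, at the 99.3rd percentile of tested genes, with a log2 fold change of −0.065 (SE 0.15, limma adjusted p = 0.888; exact permutation p = 0.7). Transcript levels at the mouse Tnfaip3 gene thus do not show the A20 delivery that the labels name, and every direction given here is between libraries as labelled. A vector sequence of another species would not be counted in full at these genes.

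**Figure D1:**
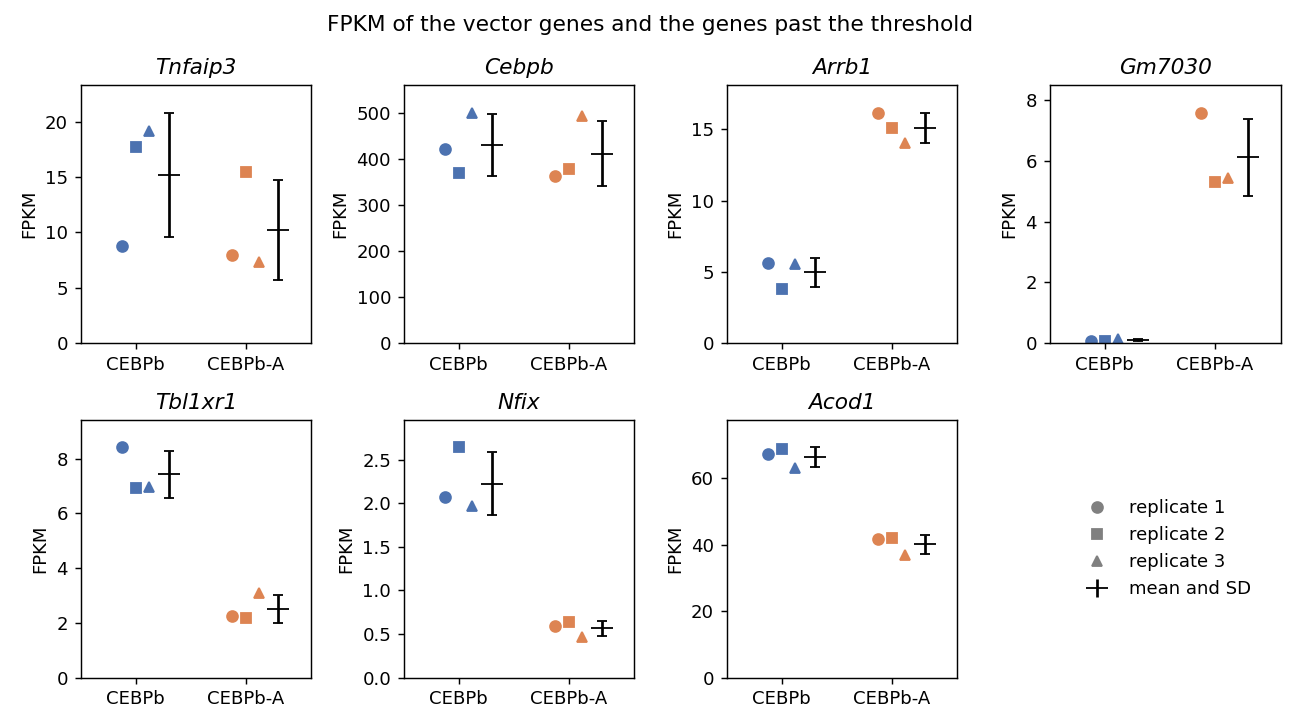
FPKM (vertical axis, from 0) of Tnfaip3, Cebpb and the 5 genes past the threshold in each library, by group (horizontal axis), with symbols for replicates 1 to 3 and the mean with its SD beside them. The groups overlap for Tnfaip3 and Cebpb and are apart for the other 5 genes, for example 14.0 to 16.2 FPKM of Arrb1 in CEBPb-A against 3.77 to 5.61 in CEBPb.

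In the libraries labelled CEBPb-A, Arrb1 and Gm7030 rose and Tbl1xr1, Nfix and Acod1 fell, the 5 genes of 9617 past the threshold. Arrb1, which encodes β-arrestin 1, an adaptor that quenches and internalises G protein-coupled receptors, reached 15.1 ± 1.08 FPKM against 4.97 ± 1.03, a 3.04-fold higher mean (SD, n = 3 each; log2 fold change 1.45, SE 0.14, limma adjusted p = 0.0368). Acod1, the enzyme that makes itaconate in activated macrophages, stood at 40.1 ± 2.86 FPKM against 66.3 ± 2.99, so the CEBPb mean was 1.65-fold higher (log2 fold change −0.71, SE 0.08, adjusted p = 0.0495). Tbl1xr1, a subunit of nuclear receptor corepressor complexes, stood at 2.51 ± 0.499 FPKM against 7.43 ± 0.854 (log2 fold change −1.27, SE 0.13, adjusted p = 0.0368). Nfix, a transcription factor of the nuclear factor I family, stood at 0.565 ± 0.0860 against 2.23 ± 0.364 (log2 fold change −1.04, SE 0.11, adjusted p = 0.0368). Gm7030, a gene in the region of MHC class I genes that was named after its values were seen, stood at 6.12 ± 1.28 FPKM against 0.0916 ± 0.0385 (log2 fold change 2.69, SE 0.13, adjusted p = 6.0e-04). Its exons overlap a pseudogene of an MHC class I gene on the same strand, so reads may be shared among such copies and its level is uncertain. The 3 libraries of each group did not overlap for any of the 5 genes. Their positions are Arrb1 (ENSMUSG00000018909.15) on chromosome 7 from 99535466 to 99606771, Acod1 (ENSMUSG00000022126.6) on chromosome 14 from 103046977 to 103056573, and Tbl1xr1 (ENSMUSG00000027630.13) on chromosome 3 from 22076652 to 22216594. Nfix (ENSMUSG00000001911.16) lies on chromosome 8 from 84699876 to 84800344 and Gm7030 (ENSMUSG00000092243.8) on chromosome 17 from 36109719 to 36129425. Values cover each whole gene, not single exons. Gm7030 passed with each library left out in turn, whereas the other 4 did not: adjusted p reached 0.129 for Arrb1, 0.154 for Tbl1xr1 and Nfix and 0.337 for Acod1. With the replicate block Gm7030 passed and the other 4 did not (adjusted p = 0.1202 for Arrb1, Nfix and Acod1 and 0.136 for Tbl1xr1). The count with single libraries left out was 3, 4 and 2 without CEBPb replicates 1, 2 and 3 and 1, 3 and 9 without CEBPb-A replicates 1, 2 and 3, with 1, 2, 1, 1, 1 and 4 of the 5 genes among them.

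At an unadjusted p under 0.05 there were 787 genes (362 higher and 425 lower in CEBPb-A) where 481 would pass by chance, while 2 other splits of the same libraries gave 830 and 815. The groups did not overlap for 1611 genes, 16.8% against the 10% that chance gives. That 10% is an average over splits, and genes vary together between libraries. The share was not computed for the other splits, so whether it exceeds theirs was not tested. Among genes that did not pass, those with the smallest p and a higher mean in CEBPb-A were Hyal2 (3.08 ± 0.392 against 1.45 ± 0.146 FPKM, n = 3 each, limma adjusted p = 0.171), Sap25, Cdk2ap1, Fcor and Hmg20b, with log2 fold changes of 0.73, 0.50, 0.61, 0.51 and 0.46. Those with a lower mean were the neutrophil-attracting chemokine Cxcl2 (8.53 ± 0.650 against 14.3 ± 0.489 FPKM, n = 3 each, limma adjusted p = 0.0738), the collagen cross-linking enzyme Lox, the acute phase protein Saa3, the heat shock protein Hspa1b and the IκB-family gene Nfkbiz. Their log2 fold changes were −0.69, −0.97, −0.75, −0.88 and −0.60.

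Genes of NF-κB feedback and the NF-κB subunits fell as a list in the libraries labelled CEBPb-A. The mean log2 fold change was −0.14 over 27 genes (camera adjusted p = 9.6e-04), with 21 of 27 negative and 7 separated downward against 0 upward. The call was lost in the camera test with an estimated correlation (adjusted p = 0.266) and with fry (adjusted p = 0.0613, mixed 0.0193). The estimate itself, 0.0093, was not above the preset 0.01, so correlation among members does not account for the loss in the camera test. The shift was present in each of the 3 CEBPb-A libraries (−0.14, −0.095 and −0.18 against the CEBPb mean). None of its members passed over all genes tested, and 1 passed when adjusted over the list alone, Nfkbiz (5.25 ± 0.570 against 8.45 ± 0.307 FPKM). Beside it stood Birc3, a ubiquitin ligase of TNF receptor complexes, at −0.37, the caspase-8 inhibitor Cflar at −0.41 and the mitochondrial superoxide dismutase Sod2 at −0.21 (log2 fold changes, not past the threshold). These members were named for their small p. Others lay near 0, such as the feedback gene Nfkbia at −0.0058 and the subunit Rela at −0.047, and 6 of 27 were positive. The list of A20 partners and linear ubiquitin machinery did not pass (20 genes, mean −0.056, camera adjusted p = 0.509), with Map3k7 at −0.63 and Otulin at 0.18.

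Several inflammatory mediators had lower means in CEBPb-A, although their lists did not pass and held genes of both signs (4 of 11 chemokines and 5 of 10 cytokines positive). Of 11 chemokines (mean −0.14, camera adjusted p = 0.201; −0.17, −0.074 and −0.17 in CEBPb-A replicates 1, 2 and 3), 3 passed downward when adjusted over the list alone, and 0 over all genes tested. These were Cxcl2, Ccl3 (103 ± 12.6 against 147 ± 4.21 FPKM, n = 3) and Cxcl1 (2.76 ± 0.628 against 5.17 ± 0.833 FPKM, n = 3), while Ccl6, also an alveolar macrophage marker, had a log2 fold change of 0.29. Of 10 cytokines (mean −0.068, camera adjusted p = 0.508), 2 passed downward when adjusted over the list alone, Il1a (46.7 ± 2.90 against 62.5 ± 3.76 FPKM, n = 3) and Tnf (23.3 ± 1.07 against 30.3 ± 1.77 FPKM, n = 3). The IL-1 receptor antagonist Il1rn stood at 7.98 ± 0.260 against 6.46 ± 0.575 FPKM and did not pass. Fry's mixed test, which asks for change in either direction, gave adjusted p = 2.5e-04 for chemokines and 2.3e-05 for cytokines, and its directional test 0.0957 and 0.476. Without CEBPb-A replicate 3, Ccl3 passed over all genes tested (log2 fold change −0.62, limma adjusted p = 0.0499). In the 18 other alternatives Ccl3 did not pass.

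**Figure D2:**
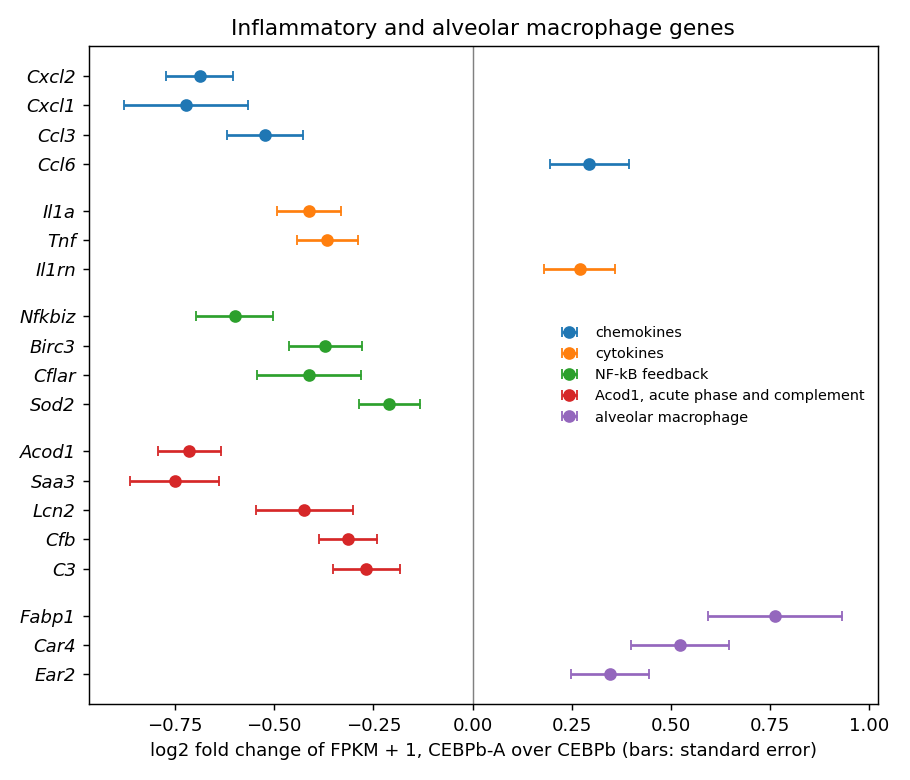
Log2 fold change of FPKM + 1, CEBPb-A over CEBPb (horizontal axis), with its standard error, for named genes (vertical axis) coloured by group. Of these only Acod1 passed over all genes tested, while Cxcl2 lies at −0.69 and Fabp1 at 0.76. Apart from Acod1, the genes were picked among the members with the smallest p in their lists, so the spread of whole lists is not shown.

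In the list of C/EBP family and C/EBP-linked myeloid genes (20 genes, mean −0.038, median 0.036, camera adjusted p = 0.764, fry mixed adjusted p = 0.0041), 1 gene passed upward and 1 downward when adjusted over the list alone. These were Fcgr4, an activating Fc receptor (92.0 ± 2.34 against 73.0 ± 5.80 FPKM), and Saa3 (1.83 ± 0.331 against 3.73 ± 0.223 FPKM), with the siderophore binder Lcn2 at −0.42 and the complement protein C3 at −0.27. In the list of Fcγ receptors and complement (16 genes, mean −0.049, camera adjusted p = 0.579, fry mixed adjusted p = 0.0123), 1 passed upward and 1 downward when adjusted over the list alone, Fcgr4 and complement factor B, Cfb (287 ± 13.5 against 357 ± 11 FPKM).

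Alveolar macrophage identity genes rose as a list in CEBPb-A, by a mean of 0.11 over 30 genes (camera adjusted p = 1.2e-03), with 23 positive, 8 separated upward and 2 downward. The call was lost in the camera test with an estimated correlation (adjusted p = 0.266), with fry (adjusted p = 0.0613) and after quantile normalization (mean 0.050, camera adjusted p = 0.2998). The estimated correlation was −0.0025, below the preset 0.01, so correlation among members does not account for the first of these losses. The 3 CEBPb-A libraries gave 0.093, 0.099 and 0.15. The median transcript of the list had 1544 bases (Fabp1 553, Car4 994, Ear2 719). Across all tested genes fold changes were lower for longer transcripts (Spearman rho −0.43, genes not being independent replicates). With length and GC trends removed the mean of the list stayed at 0.11 and the list passed at the preset correlation. Of its members 0 passed over all genes tested and 2 passed upward when adjusted over the list alone, the fatty acid binding protein Fabp1 (10.1 ± 1.62 against 5.603 ± 1.30 FPKM) and the carbonic anhydrase Car4 (66.5 ± 11.2 against 45.6 ± 2.08 FPKM). The ribonuclease Ear2 stood at 918 ± 78.2 against 722 ± 50.6 FPKM and did not pass. These members were named for their small p, and the rise was not shared by all identity markers. Siglecf had a log2 fold change of 0.016. The 7 negative members included Siglec1 at −0.39, Marco at −0.105 and Itgax at −0.11, none past the threshold.

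Type I interferon response genes fell and genes of oxidative phosphorylation and of the cytosolic ribosome rose as lists in CEBPb-A, to very different extents in its 3 libraries. With an estimated correlation none of the 3 calls held (adjusted p = 0.508 for interferon, 0.508 for oxidative phosphorylation and 0.608 for ribosomal proteins), nor with fry (adjusted p = 0.361, 0.309 and 0.454). The interferon list had a mean log2 fold change of −0.41 over 34 genes (camera adjusted p = 5.0e-13), with 33 negative and 13 separated downward. No member passed, over all genes tested or adjusted over the list alone; Oasl2, Bst2, Ifi204 and Irf7 had log2 fold changes of −0.66, −0.45, −0.51 and −0.43. Its mean was −0.092, −0.38 and −0.75 in CEBPb-A replicates 1, 2 and 3 and −0.11, 0.10 and 0.011 in CEBPb replicates 1, 2 and 3, so the groups overlapped, and the fold change was −0.24 without CEBPb-A replicate 3. Oxidative phosphorylation had a mean of 0.15 over 32 genes (camera adjusted p = 1.5e-07; Cycs at 0.28, not past the threshold) and 0.083 without that replicate. Cytosolic ribosomal proteins had a mean of 0.18 over 32 genes (camera adjusted p = 3.7e-09; Rpl32 at 0.23 and Rps19 at 0.20, not past the threshold) and 0.066 without it, with 32 of 32 positive and no member past the threshold. Fold changes also followed transcript length across genes (Spearman rho −0.43, and −0.26 without CEBPb-A replicate 3; genes are not independent replicates). The median transcript was 798 bases for the ribosomal list, 730.5 for oxidative phosphorylation and 2076 for interferon genes.

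**Figure D3:**
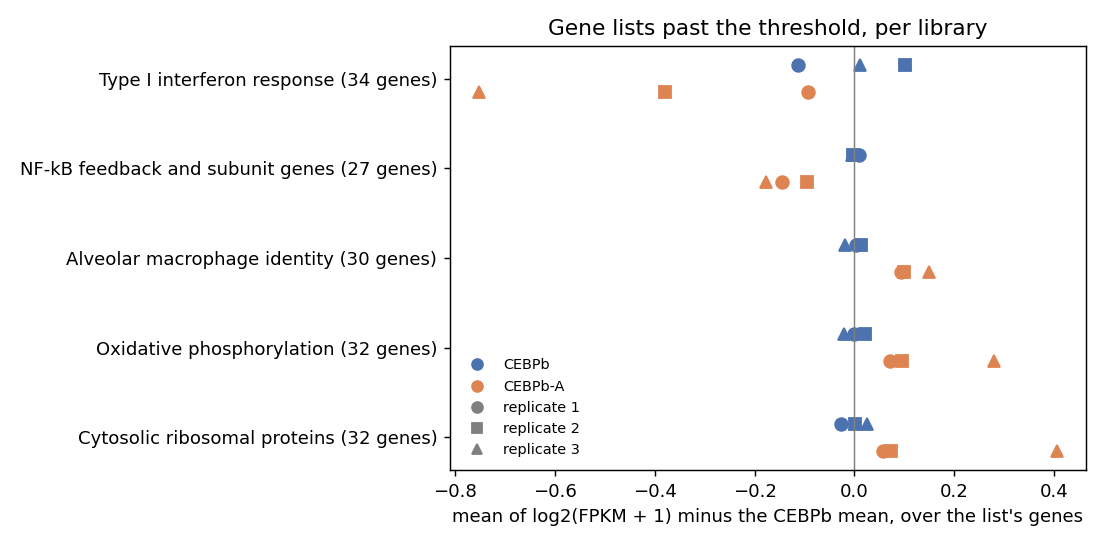
Mean of log2(FPKM + 1) minus the CEBPb mean (horizontal axis) over the genes of each list past the threshold (vertical axis), one symbol per library, coloured by group. CEBPb-A replicate 3 lies farthest out in each list, at −0.75 for interferon genes and 0.41 for ribosomal proteins, while the NF-κB list spans −0.095 to −0.18.

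**Figure D4:**
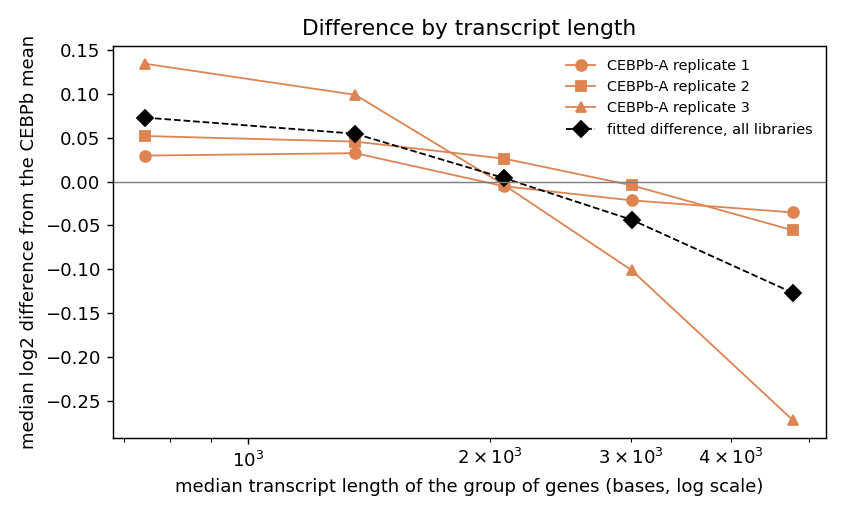
Median log2 difference from the CEBPb mean (vertical axis) against median transcript length in bases (horizontal log axis) for tested genes in 5 equal groups by length, for each CEBPb-A library and for the fitted difference. The fitted median runs from 0.073 for the shortest to −0.13 for the longest genes, and CEBPb-A replicate 3 reaches −0.27.

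Of the stress lists, heat shock did not pass as a list (14 genes, mean −0.15, median −0.031, 6 positive, camera adjusted p = 0.143, fry mixed adjusted p = 0.0075), but 3 members passed downward when adjusted over the list alone. They were the inducible HSP70 genes Hspa1b (4.88 ± 0.603 against 9.90 ± 1.61 FPKM) and Hspa1a (3.43 ± 0.581 against 7.18 ± 1.48 FPKM), near-identical copies whose reads cannot be told apart with certainty, and their cochaperone Hsph1 (8.01 ± 0.116 against 10.04 ± 0.530 FPKM). The 2 HSP70 genes may thus not be separate measurements, although the list counts both. NRF2 oxidative stress genes had a mean of 0.090 (24 genes, camera adjusted p = 0.0516; Slc7a11 at −0.46 and Gstm1 at 0.37). Interferon gamma response and MHC class I genes had a mean of −0.17 (23 genes, camera adjusted p = 0.0646; Gbp7 at −0.83, Gbp2 at −0.47 and Tap1 at −0.46). These 3 lists passed, at the preset correlation, with some single libraries left out: heat shock without CEBPb replicate 2 (−0.19) or CEBPb-A replicate 3 (−0.18), and interferon gamma without CEBPb replicate 1 (−0.20) or CEBPb-A replicate 3 (−0.16). NRF2 genes did so without CEBPb replicate 1 (0.115) or 2 (0.089), or CEBPb-A replicate 1 (0.12) or 2 (0.13). Without CEBPb-A replicate 3 the NRF2 mean was only 0.023 and the list did not pass. With all 6 libraries and an estimated correlation the adjusted p was 0.613 for heat shock, 0.508 for interferon gamma and 0.669 for NRF2. In the p53 and apoptosis list (22 genes, camera adjusted p = 0.865) Apaf1, the apoptosome scaffold, passed downward when adjusted over the list alone (4.70 ± 0.786 against 7.84 ± 0.367 FPKM), with the apoptosis inhibitor Bcl2l1 at 0.54. In the list of matrix genes and proteases (15 genes, camera adjusted p = 0.764) the membrane metalloprotease Mmp14 passed downward when adjusted over the list alone (3.06 ± 0.407 against 4.86 ± 0.665 FPKM), with Spp1, osteopontin, at 0.33. The mean of this list was −0.0053 while camera's direction was upward.

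No other list of biology passed, and 0 of their members did, over all genes tested or over the list alone. Their means and camera adjusted p were as follows. Toll-like receptor and inflammasome components had −0.044 (0.309; Nlrp3 −0.36, Casp4 −0.27), early response genes of MAP kinases and AP-1 had 0.064 (0.201; Fos 0.31, Maff 0.76) and alternative activation had −0.061 (0.509; Irf4 −0.34). MHC class II presentation had 0.0086 (0.579; H2-DMb1 0.18), cholesterol biosynthesis had 0.022 (0.509; Ebp 0.35, Msmo1 −0.37) and lipid uptake, efflux and oxidation had 0.042 (0.201; Plin2 0.20, Abca1 −0.47). Glycolysis and hypoxia had 0.034 (0.201; Tpi1 0.27, Ldha 0.22, Hif1a −0.29), the unfolded protein and integrated stress responses had −0.042 (0.764; Atf6 −0.33) and the cell cycle had 0.025 (0.404; Pcna 0.13). Lysosome and autophagy genes had 0.021 (0.462; Atp6v0d1 0.17, Tfeb 0.44), and this mean turned to −0.026 after quantile normalization. Mitochondrially encoded genes had 0.14 (0.172; mt-Co2 0.20), and their share of FPKM, 3.78% to 6.48% per library, was highest in replicate 2 of both groups; the list passed without CEBPb replicate 2 (0.40, adjusted p = 2.2e-05) or CEBPb-A replicate 3 (0.21, adjusted p = 0.0200), both at the preset correlation. With all 6 libraries its estimated correlation was 0.762, which gave adjusted p = 0.706. Without CEBPb-A replicate 3 the Toll-like receptor mean was 0.024. Some of these gene values also moved much with single libraries left out: Maff from 0.49 to 1.15, Abca1 from −0.63 to −0.24 and Tfeb from 0.22 to 0.59. For Maff the groups overlapped, with 3.15, 9.38 and 4.16 FPKM in CEBPb replicates 1, 2 and 3.

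With all 6 libraries no list of markers of other lung cells passed. Neutrophil markers had a mean of 0.17 over 6 genes (camera adjusted p = 0.130), led by S100a8, which alveolar macrophages can also express, at 295 ± 8.35 FPKM against 233 ± 29.7, and Mmp8 at 59.9 ± 7.91 against 51.6 ± 4.84; without CEBPb-A replicate 3 this list passed at the preset correlation (mean 0.17, camera adjusted p = 0.0123). With all 6 libraries and an estimated correlation its adjusted p was 0.508 (fry 0.284). Epithelial markers had a mean of 0.14 over 8 genes (camera adjusted p = 0.312, Hopx at 0.30), with the club cell protein Scgb1a1 at 38.3 ± 18.3 against 27.9 ± 5.61 FPKM. The epithelial mean was 0.070, 0.014 and 0.34 in CEBPb-A replicates 1, 2 and 3, and 0.042 with replicate 3 left out. Markers of recruited monocytes and interstitial macrophages had −0.12 over 6 genes (adjusted p = 0.607), with Apoe at 201 ± 18.1 against 177 ± 26.8 FPKM and C1qa at 1.81 ± 0.216 against 2.60 ± 0.363. Too few members were tested for dendritic cells (1), T and NK cells (2, with Cd2 at 19.9 ± 2.77 against 17.2 ± 1.33 FPKM), B cells (1), eosinophils, basophils and mast cells (1), endothelium (2) and fibroblasts (2), and 0 of 10 red cell markers were listed.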

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

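The removal of length and GC trends, that removal without CEBPb-A replicate 3, and the exclusion of overlapping genes were chosen after seeing the data; the other alternatives were planned. Over 20 alternatives the count of genes past the threshold (5; 2 higher, 3 lower) ran from 0 to 9. With each library left out it ran from 1 to 9 (1 to 4 higher, 0 to 5 lower), with a mean FPKM of at least 5 it was 0 (0 higher, 0 lower; limma, 522 at an unadjusted p under 0.05), since Gm7030, Nfix and Tbl1xr1 are then not tested and Arrb1 and Acod1 had adjusted p of 0.0623 and 0.0805, and after quantile normalization it was 2 (0 lower). The labels state no pairing, and the main fit holds none. Deviations of same-numbered libraries correlated at 0.0993, 0.247 and 0.259, and 6 of 6 libraries correlated best with their own number. An effect shared by libraries of the same number therefore stays open. With the replicate block the counts were 1 gene (1 higher, 0 lower, with 1285 at an unadjusted limma p under 0.05) and 8 lists. The lists gained by the block were interferon gamma, NRF2 and mitochondrial genes (camera adjusted p = 0.0456, 0.022 and 0.0039). Gm7030 passed in 18 of 18 alternatives that tested it, Arrb1 in 13 of 19, Tbl1xr1 in 10 of 18, Nfix in 8 of 18 and Acod1 in 7 of 19, each with 1 direction throughout; Lox passed once the trends were removed (−0.84, adjusted p = 0.0324). The Tnfaip3 log2 fold change ran from −0.86 to −0.33 and never passed, that of Cebpb from −0.20 to 0.051 with libraries left out. The 5 lists past the threshold became 0 with an estimated correlation and 0 with fry (means as reported: −0.14, −0.41, 0.11, 0.15 and 0.18), 5 to 9 with libraries left out, and 8 with trends removed and CEBPb-A replicate 3 left out, where ribosomal proteins no longer passed (0.033, adjusted p = 0.0702); macrophage identity was lost after quantile normalization (0.050, adjusted p = 0.2998) and stood at 0.11 with trends removed (adjusted p = 0.0028). Heat shock, interferon gamma, NRF2, mitochondrial and neutrophil lists passed under some settings, 25 times in all, in 1 direction each. With a mean of at least 5 the neutrophil and monocyte lists had too few genes to test. Signs turned only for values that did not pass. The matrix list gave 0.0047 without a filter, 0.0077 with a mean of at least 5, 0.011 with median-of-ratios scaling, 0.038 with trends removed, 0.051 also without CEBPb-A replicate 3, and −0.044 to 0.036 with libraries left out. The p53 list gave 0.0046 with median-of-ratios scaling, 0.0099 and 0.012 with trends removed (all libraries, then without that replicate) and −0.029 to 0.016 with libraries left out. Cell cycle gave −0.0055 with a mean of at least 5, lysosome −0.026 after quantile normalization, MHC class II −0.026 with trends removed and, with that replicate also left out, Toll-like receptors 0.023, Csf3r 0.036 and Scgb1a1 −0.0021. With libraries left out, Csf3r ran from −0.14 to 0.0068, MHC class II from −0.019 to 0.047, C/EBP-linked genes from −0.084 to 0.0064, Toll-like receptors from −0.10 to 0.024, cholesterol from −3.2e-04 to 0.038 and mitochondrial genes from −0.043 to 0.40. Beyond the smaller number of libraries or genes, the cause of these changes was not tested. Unknown depth leaves the counting error of low genes such as Nfix unmeasured.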

Other observations

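The tests of explanations in this part and the counts over splits were chosen after the results were seen; leaving out libraries and the estimated correlation were planned. Among the 10 splits of the 6 libraries into 3 and 3, the unadjusted camera p of the NF-κB list was 1.3e-04 for the labelled split and 0.0058 at the lowest among the others, and that of macrophage identity genes was 2.0e-04 against 0.010; in both cases 1 split, the labelled one, reached its value, and 2 and 3 of the 9 other splits had an unadjusted p under 0.05. For interferon genes 6 of the 9 other splits gave an unadjusted p under 0.05, the lowest 1.7e-25 against 1.7e-14 for the labelled split, and 2 splits reached the labelled value. For ribosomal proteins 9 of the 9 did (lowest 5.5e-11 against 2.5e-10, 2 splits reaching the labelled value), and for oxidative phosphorylation 8 of the 9 (lowest 1.8e-07 against 1.6e-08, 1 split). The labelled split called 5 genes and the highest of the others 6, so that 2 of the 10 splits gave at least 5; it called 5 lists and the highest of the others 5, with 4 splits giving at least 5. At an unadjusted p under 0.05 the labelled split gave 787 genes, fewer than CEBPb replicates 1 and 2 with CEBPb-A replicate 1 against the rest (830) or with CEBPb-A replicate 2 against the rest (815). With 10 splits no share can fall under 0.05.

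Tnfaip3 was not higher where the labels name A20 delivery. An exchange of libraries between the groups stays open: the highest Tnfaip3 value was 2.62 times the lowest, and no source used here gives the level that delivery should reach. A vector coding sequence of another species, not counted at the mouse gene, may also give the log2 fold change of −0.53, and cannot be told apart from absent delivery without reads. No biological explanation was tested.

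The lower interferon list and the higher ribosomal and oxidative phosphorylation lists rest in part on CEBPb-A replicate 3. With length and GC trends removed the interferon mean was −0.39, 95.1% of its value before, and still passed at the preset correlation, which argues against those trends as the whole cause, although an estimated correlation ends the call (adjusted p = 0.508 before their removal). For ribosomal proteins the same removal left 0.12 (65.4%) and for oxidative phosphorylation 0.10 (69.5%), which decides neither way; with CEBPb-A replicate 3 also left out ribosomal proteins stood at 0.033 and no longer passed (camera adjusted p = 0.0702). Leaving out CEBPb-A replicate 3 left −0.24, 0.066 and 0.083 for the interferon, ribosomal and oxidative phosphorylation lists (57.7%, 36.7% and 55.8%), which still passed at the preset correlation (camera adjusted p = 2.8e-12, 2.7e-04 and 6.6e-04) but with all 6 libraries not at an estimated one (adjusted p = 0.508, 0.608 and 0.508), so that this 1 library may account for a large part of each and an effect of the group cannot be told apart from it. Whether A20 delivery changed interferon genes to different extents in the 3 libraries was not tested.

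An effect of A20 on the lower NF-κB feedback list is a hypothesis that was not tested, and its direction holds only for the libraries as labelled. The camera test with an estimated correlation ends the call (adjusted p = 0.266). The estimate, 0.0093, was not above the preset 0.01, so this loss is no evidence of correlation among members. Removing length and GC trends left a mean of −0.12 (87.1%, camera adjusted p = 3.5e-05) and leaving out CEBPb-A replicate 3 left −0.12 (86.4%, camera adjusted p = 6.6e-05), so at the preset correlation neither is likely the whole cause. The neutrophil marker mean was 0.17 and did not pass (camera adjusted p = 0.130, 0.0123 without CEBPb-A replicate 3, 0.508 with all 6 libraries and an estimated correlation). It was 0.19, 0.15 and 0.15 in CEBPb-A replicates 1, 2 and 3 against 0.054, −0.049 and −0.0049 in those of CEBPb. Of its 6 genes 5 were positive, with the receptor Csf3r at −0.076. The list did not pass, so these values do not decide whether CEBPb-A held a smaller share of neutrophils. The virus load, the state of the cells at isolation and the control virus stay open, since the labels do not give them.

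One overlapping pair, named after its values were seen, had mean differences of opposite sign and did not pass (limma adjusted p = 0.588 for AC149222.1 and 0.356 for Hsd3b7), except with CEBPb replicate 2 left out (9.0e-04 and 0.0038). The read-through gene AC149222.1 (chromosome 7, 127785608 to 127803802) had 12.3, 12.9 and 17.3 FPKM in CEBPb-A and 0.047, 9.49 and 0.061 in CEBPb, while Hsd3b7, which ends at the same base, had 8.14, 9 and 8.13 against 26.2, 13.9 and 28.3. Reads may be shared between these 2 genes. Opposite changes of the genes therefore cannot be told apart from a different division of reads between them. Among 292 tested genes whose exons overlap another listed gene, 4.11% had a within-group SD above 1 (log2), against 0.0965% of 9325 others.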
